A study of Mus musculus with 16 samples.

How the data were processed

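Total RNA of 16 E0771-luciferase tumours from female C57BL/6J mice on a high-fat diet was used, 8 from mice given anti-PD-1 and 8 from mice given IgG2a. Per the labels' protocols, RNA was extracted with a column kit, samples with an RNA integrity number above 5 were kept, poly(A) RNA was enriched with oligo-dT beads, and libraries were made with a non-directional kit, so reads from a gene and an antisense partner cannot be told apart. The deposited values are estimated counts of reads per transcript, which need not be whole, per the file headers. The same tables hold the authors' TPM, scaled per tumour, and, as other columns, transcript length and effective length, per the file headers. The submitters' processing notes name the build GRCm38 and the tools edgeR and limma. The quantifier, its version and the annotation used by the authors are not given in the sources used here. Per the deposited tables, 25.4 to 38.6% of the transcripts had a value that was not whole, so reads shared between similar transcripts, isoforms of a gene included, had been divided among them. How far this affects paralogs and ribosomal protein genes with processed copies was not measured.

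Transcripts were matched by identifier to the GENCODE vM21 annotation of GRCm38, which placed 114200 of 115088 transcripts in 47311 genes. Between 0.167 and 0.217% of a tumour's estimated reads belonged to transcripts with no match and were left out. Estimated counts were summed per gene and rounded to whole numbers. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), leaving 16154, scaled with TMM factors and tested with edgeR 4.0.16 in R 4.3.3 by the robust quasi-likelihood test, anti-PD-1 over IgG2a, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are log2 with SE from the same fit, CPM values are means ± SD over tumours, and intervals of a fold change are at 95%. The biological coefficient of variation was 0.536. Mitochondrially encoded transcripts were not analysed here, and in place of their share the reads of 7 pseudogenes on chromosome 1 that match them at 99.7 to 100% identity by blastn 2.17.0 were used as a library measure, which averaged 1.43 ± 0.533% under anti-PD-1 and 1.41 ± 0.680% under IgG2a (SD, n = 8 each, exact permutation p = 0.961). The other library measures were total reads, genes detected, with 20084 ± 831 under anti-PD-1 and 20679 ± 608 under IgG2a (exact permutation p = 0.120), transcripts detected, the share of the 10 most abundant genes, at 5.20 ± 0.289% and 5.34 ± 0.598% (exact permutation p = 0.592), and the length correlation.

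The groups, the tests, the 43 gene lists, the rule for named genes and most alternatives were chosen before the data were examined. A list score is the mean log2 CPM (prior count 2) of its tested members, compared between groups by a two-sided exact permutation test over all 12870 assignments of the tumours, with adjustment over the 41 lists of 5 or more tested members. The smallest p this test can give is 1.6e-04. Skin keratinocyte genes, with 4 of 17 members tested, and mitochondrially encoded genes, with 0 of 13, were not scored. Principal components were taken from log2 CPM of the 2000 most variable genes. Named genes were, of protein-coding genes with a mean log2 CPM of at least 1 and a symbol that is neither a Gm number, a Rik name nor a receptor segment, the 10 per direction with the largest change among those passing, filled with the genes of smallest unadjusted p where fewer passed. To these were added 15 genes of checkpoint, T cell, macrophage and adipocyte biology fixed in advance, and up to 4 members of smallest p of each list described, of which 2 were used. As no gene passed, every gene of the first part was chosen by unadjusted p.

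Counts of 16154 genes were simulated from the real means and library sizes of this comparison. On these the edgeR test recovered 20% of 50 genes changed 1.5-fold, 68% of 50 changed 2-fold, 88% of 50 changed 4-fold and 98% of 50 changed 8-fold. It called 8 of 15954 unchanged genes. Each gene was drawn independently of the others, around the same mean in all tumours unless changed. Tumours that stand apart and genes that move together were not simulated, so recovery in the real data may be lower. The list test was checked on the real scores under a random regrouping of the tumours, with a shift added to 1 list at a time. It recovered 6 of 41 lists at a shift of 0.5 log2 units, 19 at 1 and 30 at 2, and called 0 with no shift. Pairs of tumours in a group had Pearson correlations of 0.794 to 0.983 across genes. No pair agreed within sampling noise, the lowest chi-square per gene being 29.6. Alternatives were other scaling factors, DESeq2 1.42.0, limma-voom with and without quality weights (limma 3.58.1), other filters, an offset for transcript length, protein-coding genes alone, the range of animal numbers as a covariate, an adjusted p of 0.1, TPM scores with pseudocounts of 1 and 0.1, camera, fry and each tumour left out in turn. Leaving out the 3 tumours that stood apart, and leaving tumours out of the means on the second component, were added after the data were seen.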

Results

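Bulk RNA was measured in 16 mammary tumours grown in obese female C57BL/6J mice. The tumours came from E0771-luciferase cells, a C57BL/6 mouse mammary cancer line that carries a luciferase reporter, of which 250000 were injected into the mammary gland numbered 4. The mice were fed a diet with 60% of its energy from fat from 8 to 26 weeks of age. From 3 days after the injection of cells they received 200 ug of antibody every 3 days until day 21. In 8 mice the antibody blocked PD-1, the inhibitory receptor on T cells encoded by Pdcd1, and 8 mice received an IgG2a isotype control. Each tumour carries its own animal number in the labels, so the replicates are separate animals. The files held 59036535 to 82591064 estimated reads per tumour, with a mean of 67699945 ± 5781141 (SD, n = 8) under anti-PD-1 and 68928894 ± 6840000 (SD, n = 8) under IgG2a (exact permutation p = 0.707). The comparison asks which transcripts of the tumour differ between checkpoint blockade and the isotype control in obese mice.

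Among the tumours, 3 stood apart from the other 13. IgG2a replicate 7 had an adipocyte gene score 7.18 log2 units above the median of the 16 tumours, an erythroid score 7.97 above it and an endothelial score 3.68 above it, while its cell cycle score lay at -1.37. IgG2a replicate 3 had a skeletal muscle score 10.57 log2 units above the median. In anti-PD-1 replicate 6 only 38993 transcripts were detected, against 47997 to 55476 in the other 15 tumours, and its ribosomal protein score lay 1.12 above the median at 74502664 reads. Transcripts detected averaged 50116 ± 4768 (SD, n = 8) under anti-PD-1 and 53448 ± 1514 (SD, n = 8) under IgG2a, with an exact permutation p of 0.0283 that became 0.155 when adjusted over 6 library measures. The rank correlation across genes between a tumour's deviation from the median and transcript length averaged -0.12 under anti-PD-1 and 0.13 under IgG2a (exact permutation p = 0.0517, adjusted p = 0.155).

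**Figure D1:**
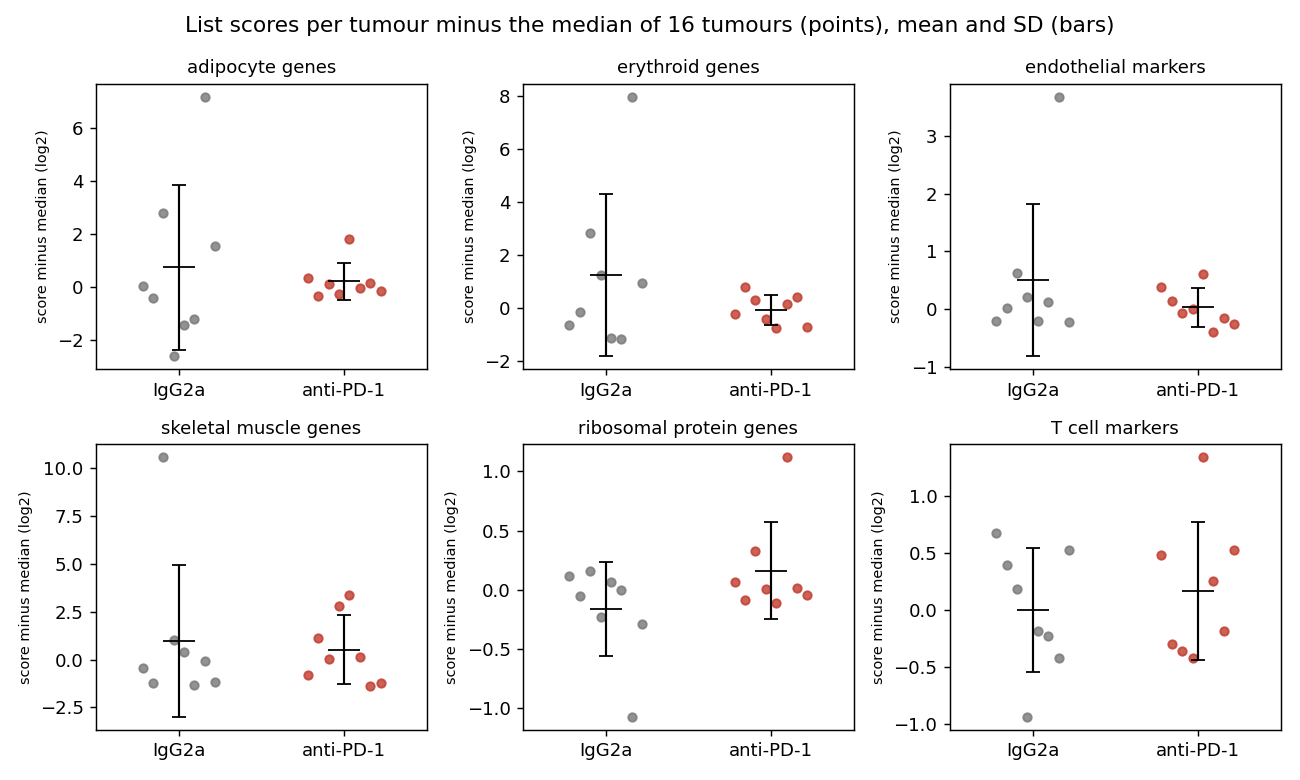
Scores of 6 gene lists in each tumour, as mean log2 CPM over the members minus the median of the 16 tumours, with points for tumours and bars for the mean and SD of 8 tumours per group. One IgG2a tumour reaches 7.18 for adipocyte genes and 7.97 for erythroid genes, another reaches 10.57 for skeletal muscle genes, and one anti-PD-1 tumour reaches 1.12 for ribosomal protein genes.

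The gene with the smallest p of all those tested was Cxcl5, with a higher estimate under anti-PD-1, a chemokine that attracts neutrophils. Cxcl5 (ENSMUSG00000029371, chromosome 5, 90759360 to 90761624 in GRCm38) averaged 8.40 ± 9.74 CPM (SD, n = 8) under anti-PD-1 and 0.656 ± 0.371 CPM (SD, n = 8) under IgG2a, a log2 fold change of 3.68 ± 0.82 (SE), and 7 of 8 treated tumours lay above the IgG2a median. The collagenase gene Mmp13 averaged 133 ± 84.6 CPM under anti-PD-1 and 54.0 ± 23.7 CPM under IgG2a (SD, n = 8 each), a log2 fold change of 1.30 ± 0.37 (SE), and 8 of 8 treated tumours lay above the IgG2a median. The Mmp13 estimate was 0.42 with limma-voom and quality weights (unadjusted p = 0.109) and 0.82 in edgeR without the 3 tumours. Lrrc15, a surface protein of activated fibroblasts, had a log2 fold change of 1.34 ± 0.42 (SE), and Kif26b one of 2.14 ± 0.60 (SE). Smaller estimates with tight errors were those of Zfpl1 at 0.32 ± 0.08, Rabggta, a subunit of Rab geranylgeranyl transferase, at 0.32 ± 0.08, Vmp1 at 0.27 ± 0.08, Lxn at 0.27 ± 0.08, Thoc1 at 0.39 ± 0.12 and Slc7a6os at 0.54 ± 0.16 (log2 fold change and SE). None of these genes passed the test: edgeR's quasi-likelihood test called 0 of 16154 genes at a Benjamini-Hochberg adjusted p of 0.05, the smallest adjusted p being 0.434. At an unadjusted p under 0.05 there were 1836 genes, 560 with higher and 1276 with lower estimates under anti-PD-1, where a share of 0.05 of the genes is 808. Limma-voom called 0 genes and 1011 at the unadjusted threshold (504 higher, 507 lower), and 0 and 3421 with quality weights (1560 higher, 1861 lower). EdgeR called 0 and 1162 without IgG2a replicate 7 (607 higher, 555 lower) and 0 and 1209 without anti-PD-1 replicate 6 (230 higher, 979 lower). DESeq2 tested 27933 genes, so the share of 808 given for 16154 genes does not apply to it. It had 1759 genes at the unadjusted threshold (765 higher, 994 lower). DESeq2 called 4 genes, Cxcl5 with a log2 fold change of 3.70 ± 0.68 (SE, adjusted p = 3.5e-04) and Igkv8-16, Gm20671 and Gm21541, which had reads in 3, 3 and 2 of the 16 tumours and were named after their values were seen.

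**Figure D2:**
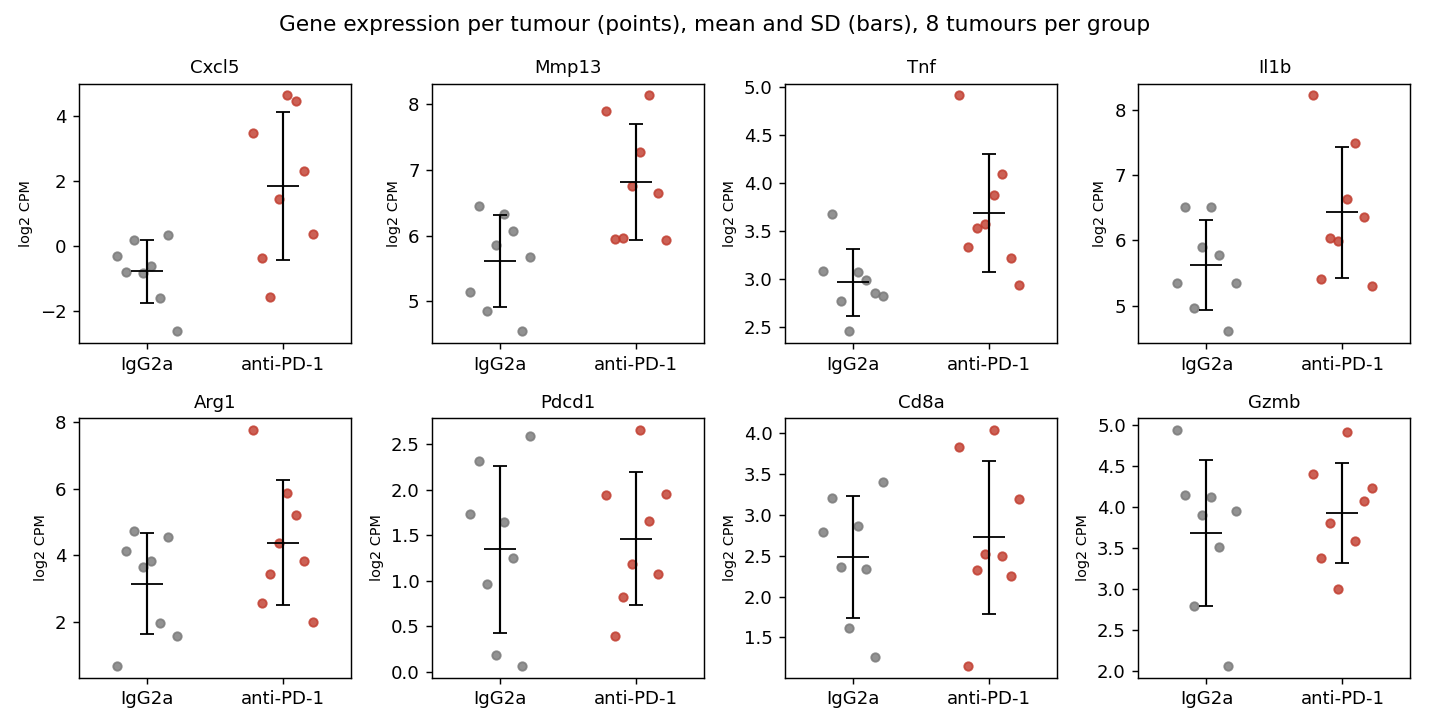
Log2 CPM of 8 genes in each tumour by group, with points for tumours and bars for the mean and SD of 8 tumours. All 8 anti-PD-1 tumours lie above the IgG2a median for Mmp13 and Tnf and 7 of 8 do for Cxcl5, while Pdcd1 is spread alike with 4 of 8 above it.

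Among genes with lower estimates under anti-PD-1, Scara5, a ferritin receptor, averaged 2.16 ± 0.92 CPM under anti-PD-1 and 8.34 ± 9.18 CPM under IgG2a (SD, n = 8 each), a log2 fold change of -1.94 ± 0.49 (SE), and 0 of 8 treated tumours lay above the IgG2a median. Adcy9, an adenylyl cyclase, had a log2 fold change of -1.43 ± 0.37 (SE), and the C-type lectin Cd209f one of -5.71 ± 1.39 (SE). Pdk4, which restrains pyruvate dehydrogenase, had an estimate of -6.91 ± 1.81 while 7 of 8 treated tumours lay above the IgG2a median, Tnxb, an extracellular matrix protein, -3.33 ± 0.89, and Alas2, the erythroid enzyme of haem synthesis, -5.46 ± 1.5 (log2 fold change and SE). Tpbgl, Camk2b, Rasd2 and Abca8a had estimates of -4.93, -3.83, -5.66 and -3.43. None passed the edgeR test after adjustment. Leaving out IgG2a replicate 7 alone gave -1.26 for Scara5, -3.74 for Cd209f, -1.13 for Tnxb, -1.04 for Alas2 and -1.51 for Abca8a, and leaving out IgG2a replicate 3 alone gave -1.19 for Camk2b and -1.41 for Rasd2. Without IgG2a replicates 3 and 7 and anti-PD-1 replicate 6, left out after their values were seen, the estimates were -1.28 for Scara5, -0.68 for Adcy9, -1.55 for Cd209f, -0.50 for Tnxb, -0.10 for Alas2, -0.42 for Camk2b, -0.57 for Rasd2, -0.46 for Abca8a, 0.17 for Pdk4 and 0.04 for Tpbgl, and edgeR again called 0 genes.

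T cell genes did not differ detectably between the groups. Pdcd1, the target of the antibody, averaged 3.05 ± 1.60 CPM under anti-PD-1 and 2.97 ± 1.77 CPM under IgG2a (SD, n = 8 each), a log2 fold change of 0.04 with a 95% interval from -0.80 to 0.88. Cd274, which encodes the ligand PD-L1, had a log2 fold change of 0.33 ± 0.30 (SE), and the other ligand gene Pdcd1lg2 one of 0.69 ± 0.44 (SE). Estimates were 0.35 ± 0.39 for Cd8a, -0.17 ± 0.46 for Cd4, -0.18 ± 0.31 for Foxp3, the regulatory T cell factor, 0.14 ± 0.34 for the protease gene Gzmb, -0.25 ± 0.30 for the pore-forming Prf1 and 0.89 ± 0.48 for Ifng, which encodes interferon gamma (log2 fold change and SE). The estimates of Pdcd1, Cd4 and Gzmb were -0.20, 0.10 and -0.08 without the 3 tumours named above, and that of Ifng 0.53. Over 27 alternative settings the estimate ran from 0.32 to 1.05 for Ifng and from 0.37 to 0.85 for Pdcd1lg2. Leaving out anti-PD-1 replicate 5 gave 0.10 for Cd8a, -0.58 for Cd4 and -0.04 for Gzmb, leaving out anti-PD-1 replicate 1 gave -0.02 for Cd274, leaving out IgG2a replicate 1 gave 0.006 for Foxp3, and leaving out anti-PD-1 replicate 6 gave -0.14 for Prf1. Of list members chosen by small p, Lat had 0.76 ± 0.41, Icos 0.61 ± 0.36, Eomes 0.69 ± 0.42 and Tox -0.70 ± 0.41 (log2 fold change and SE). Without anti-PD-1 replicate 5 these 4 estimates were 0.45, 0.34, 0.32 and -0.96. Of 19 T cell markers, 13 had higher and 6 lower estimates, and of 17 cytotoxic lymphocyte genes 16 had higher and 1 lower. In both lists 0 members were called over all genes and 0 when adjusted over the list alone. The T cell score differed by 0.17 ± 0.29 (SE, exact permutation p = 0.582), the cytotoxic score by 0.36 ± 0.30 (SE, exact permutation p = 0.253), the immune checkpoint score by 0.12, the regulatory T cell score by 0.04 and the natural killer cell score by 0.25 log2 units. Without anti-PD-1 replicate 5 the differences were -0.0015 for T cell markers, 0.21 for cytotoxic lymphocyte genes, 0.022 for immune checkpoint genes and 0.13 for natural killer cell markers, and the cytotoxic difference was 0.19 without the 3 tumours. The B cell score differed by -0.10, the dendritic cell score by -0.10 and the mast cell and eosinophil score by 0.23, none past the threshold, and mast cell and eosinophil markers by 0.066 without anti-PD-1 replicate 6. Without the same tumours the B cell and dendritic cell differences were 0.13 and 0.02. The plasma cell score differed by -0.66, and 3 of its 10 tested members passed when adjusted over the list alone, against 0 over all genes. IgG2a replicate 7 had a plasma cell score 3.15 and IgG2a replicate 3 one 2.23 above the median. The difference for plasma cell genes was -0.29 without the first and -0.42 without the second, and without these and anti-PD-1 replicate 6 it was 0.04 with 0 members past either adjustment.

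Inflammatory cytokine genes had mostly higher estimates under anti-PD-1, without passing the test as lists. Tnf averaged 14.0 ± 7.17 CPM under anti-PD-1 and 8.00 ± 2.17 CPM under IgG2a (SD, n = 8 each), a log2 fold change of 0.81 ± 0.26 (SE), and 8 of 8 treated tumours lay above the IgG2a median. Il1b had a log2 fold change of 1.01 ± 0.41 (SE) and Cxcl10, a chemokine induced by interferon, one of 0.53 ± 0.28 (SE), with 8 of 8 treated tumours above the IgG2a median for Cxcl10. The estimate of Il1b was 0.59 without anti-PD-1 replicate 1, 0.65 without the 3 tumours named above and 0.061 with limma-voom and quality weights. Nos2 stood at 0.57 ± 0.57 and Cxcl9 at 0.33 ± 0.28 (log2 fold change and SE), and each at 0.14 without anti-PD-1 replicate 1. Tnf had 0.36 with quality weights. Of 17 tested genes of M1-like, or inflammatory, macrophages 15 had higher estimates, and the score differed by 0.44 ± 0.21 (SE, exact permutation p = 0.0544, adjusted p = 0.939 over 41 lists), the smallest p of any list. Of 26 chemokine and inflammatory cytokine genes 18 had higher and 8 lower estimates, the score differed by 0.61 ± 0.36 (SE, exact permutation p = 0.114), and 1 member passed when adjusted over the list alone, against 0 over all genes. The score of TNF and NF-kB response genes differed by 0.27 ± 0.13 (SE, exact permutation p = 0.0696), with 13 of 16 estimates higher. Without the 3 tumours named above the differences were 0.27, 0.75 and 0.12 for these lists, and 3 chemokine list members passed when adjusted over the list alone.

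Among myeloid markers, Arg1, an arginase of suppressive myeloid cells, averaged 46.0 ± 71.4 CPM under anti-PD-1 and 12.9 ± 9.53 CPM under IgG2a (SD, n = 8 each), a log2 fold change of 1.84 ± 0.79 (SE, unadjusted p = 0.0335 and adjusted p = 0.434 by edgeR). Arg1 stood at 0.75 without anti-PD-1 replicate 1, at 0.83 with limma-voom and quality weights and at 2.43 without the 3 tumours that stood apart. The macrophage genes Adgre1 and Mrc1 had estimates of -0.85 ± 0.42 and -0.79 ± 0.46, and Aif1 one of 0.62 ± 0.34 (log2 fold change and SE). Without IgG2a replicate 7 Adgre1 lay at -0.17 and Mrc1 at -0.03, without the 3 tumours that stood apart at -0.07 and 0.23, and Aif1 lay at 0.33 without anti-PD-1 replicate 6. Cxcr1 and Mmp9, both expressed by neutrophils, had estimates of 1.99 ± 0.72 and 0.96 ± 0.42 (log2 fold change and SE). Cxcr1 lay near the floor, at 0.423 ± 0.353 CPM under anti-PD-1 and 0.106 ± 0.093 CPM under IgG2a (SD, n = 8 each). Mmp9 had 0.65 without anti-PD-1 replicate 4, and Cxcr1 1.65 without anti-PD-1 replicate 1. Of 15 tested neutrophil and granulocytic suppressor cell genes 13 had higher estimates, and the score differed by 0.54 ± 0.55 (SE, exact permutation p = 0.354). That difference was 0.22 without IgG2a replicate 1, which lay 2.61 below the median for neutrophil and granulocytic MDSC genes, and 0.25 without anti-PD-1 replicate 1. The macrophage score differed by 0.03 and the monocyte score by 0.02. The score of M2-like, or alternatively activated, macrophage genes differed by -0.42 ± 0.59 (SE, exact permutation p = 0.531), 2 of its members passed when adjusted over the list alone, against 0 over all genes, and IgG2a replicate 7 lay 3.66 above the median. The difference for M2-like macrophage genes was 0.036 without IgG2a replicate 7 and 0.40 without the 3 tumours that stood apart.

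Interferon response and antigen presentation genes showed no group difference past the threshold. Irgm2, an interferon-induced GTPase, averaged 86.6 ± 20.3 CPM under anti-PD-1 and 109 ± 15.7 CPM under IgG2a (SD, n = 8 each), a log2 fold change of -0.33 ± 0.14 (SE). The RNA sensors Ifih1 and Ddx58 had estimates of -0.26 ± 0.14 and -0.29 ± 0.17, and the proteasome subunit genes Psme1 and Psmb10 had 0.31 ± 0.15 and 0.56 ± 0.28 (log2 fold change and SE). Leaving out anti-PD-1 replicate 6 gave 0.16 for Psme1, 0.22 for Psmb10 and -0.18 for Ddx58. Of 24 type I interferon response genes 19 had lower estimates, with a score difference of -0.15 ± 0.15 (SE, exact permutation p = 0.327). The type I interferon response differed by -0.083 without anti-PD-1 replicate 6 and by -0.0030 (exact permutation p = 0.989) without the 3 tumours that stood apart. The interferon gamma response differed by 0.02 (exact permutation p = 0.882), MHC class I presentation by 0.12 (exact permutation p = 0.351) and MHC class II presentation by 0.12 (exact permutation p = 0.757). MHC class I antigen presentation differed by 0.051 without anti-PD-1 replicate 6. MHC class II antigen presentation differed by -0.083 without IgG2a replicate 4 and by 0.28 without anti-PD-1 replicate 4. Ciita, the activator of MHC class II genes, had a log2 fold change of -0.44 ± 0.43 (SE), and one of -0.17 without IgG2a replicate 8.

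Matrix genes split in direction. Col12a1 averaged 91.5 ± 69.0 CPM under anti-PD-1 and 39.0 ± 19.5 CPM under IgG2a (SD, n = 8 each), a log2 fold change of 1.23 ± 0.43 (SE), next to Mmp13 in the same list. Of 31 fibroblast and matrix genes 9 had higher and 22 lower estimates, with a median log2 fold change of -0.24 and a mean of -0.36, while the score differed by 0.11 ± 0.36 (SE, exact permutation p = 0.772), the opposite sign. Without the 3 tumours that stood apart the score differed by 0.53 (exact permutation p = 0.0315, adjusted p = 0.820). Sign also differed between score and members for mammary epithelial genes, whose score differed by 0.38 while 13 of 14 estimates were lower with a median of -1.17, for macrophage markers with 0.03 against a median of -0.06, for TGF-beta response with 0.06 against -0.07, for regulators of epithelial-mesenchymal transition with 0.04 against -0.53, for the hypoxia response with 0.06 against -0.01 and for regulatory T cell genes with 0.04 against -0.11. Single tumours moved these scores: mammary epithelial genes differed by 0.056 without IgG2a replicate 5 and by 1.02 without IgG2a replicate 7, and by 1.12 without the 3 tumours. Without IgG2a replicate 7 the hypoxia response differed by 0.0012, fibroblast and matrix genes by 0.39, macrophage markers by 0.26, TGF-beta response by 0.19 and epithelial-mesenchymal transition regulators by 0.33, and without anti-PD-1 replicate 5 by 0.12, -0.030, -0.070, -0.017 and -0.11. The mean log2 fold change was of the opposite sign to the score for interferon gamma response at -0.04, glycolysis at -0.05, monocyte markers at -0.22 and, just below 0, lipid and cholesterol synthesis at -6.5e-04. Camera gave the direction opposite to the score for immediate early genes, p53 response and apoptosis and regulators of epithelial-mesenchymal transition, and fry for mammary epithelial, fibroblast and matrix, macrophage and transition genes.

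Fat, muscle and blood genes had lower estimates under anti-PD-1, and their highest counts lay in single IgG2a tumours. Adipoq, the adipokine adiponectin, averaged 3.18 ± 3.44 CPM under anti-PD-1 and 100.5 ± 271 CPM under IgG2a (SD, n = 8 each), and IgG2a replicate 7 alone held 712 CPM. Lep, which encodes leptin, had a log2 fold change of -4.46 ± 1.59 (SE) in all tumours and 1.09 without the 3 that stood apart, and the adipocyte genes Slc2a4 and Plin4 moved from -4.26 and -5.42 to 0.46 and 0.73. All 18 tested adipocyte genes, 17 skeletal muscle genes and 7 erythroid genes had lower estimates and passed when adjusted over the list alone, against 0 over all genes. Their scores differed by -0.53 ± 1.13, -0.47 ± 1.54 and -1.30 ± 1.10 log2 units (SE, exact permutation p = 0.710, 0.872 and 0.292). Adipocyte genes differed by 0.39 without IgG2a replicate 7, and skeletal muscle genes by 0.90 without IgG2a replicate 3. Without the 3 tumours 0 members of these lists passed either adjustment and the score differences were 0.91, 1.06 and 0.06. The endothelial score differed by -0.48, the pericyte and smooth muscle score by -0.39, the lymphatic endothelial score by -0.47 and the Schwann cell and nerve score by -0.61, and IgG2a replicate 7 was the highest tumour in each. Without it endothelial markers differed by -0.02, pericyte and smooth muscle markers by 0.01, lymphatic endothelial markers by -0.03, Schwann cell and nerve genes by -0.26 and erythroid genes by -0.33. The first 4 of these differences were 0.13, 0.26, 0.30 and 0.07 without the 3 tumours. In the lymphatic and in the Schwann cell list 1 member passed when adjusted over the list alone, against 0 over all genes, and without the 3 tumours these counts were 2 and 0.

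Housekeeping and metabolic lists showed small differences. All 35 ribosomal protein genes had higher estimates under anti-PD-1, with a score difference of 0.32 ± 0.20 (SE, exact permutation p = 0.139) that was 0.19 without anti-PD-1 replicate 6, 0.19 without IgG2a replicate 7 and 0.08 without the 3 tumours. Cell cycle genes differed by 0.22 ± 0.18 (SE, exact permutation p = 0.149), with IgG2a replicate 7 at -1.37 from the median, by 0.05 without that tumour and by 0.03 without the 3 tumours. The unfolded protein response differed by 0.13, oxidative phosphorylation by 0.15, fatty acid oxidation by -0.32, lipid and cholesterol synthesis by 0.12, glycolysis by 0.03, immediate early genes by -0.06 and p53 response and apoptosis by -0.06 log2 units. Leaving out IgG2a replicate 7 gave 0.080 for the unfolded protein response, 0.0064 for lipid and cholesterol synthesis, -0.11 for glycolysis and 0.049 for immediate early genes. The unfolded protein response differed by 0.071 and lipid and cholesterol synthesis by -0.083 without the 3 tumours. For fatty acid oxidation IgG2a replicates 7 and 3 lay 1.47 and 1.23 above the median, and the difference was -0.16 without the first, -0.19 without the second and -0.02 without the 3 tumours. Anti-PD-1 replicate 6 lay 0.91 above the median for oxidative phosphorylation, where Cox4i1 had a log2 fold change of 0.45 ± 0.26 (SE) and Uqcrc2 one of -0.26 ± 0.14 (SE). Oxidative phosphorylation differed by 0.038 and Cox4i1 had 0.11 without this tumour, and Uqcrc2 had -0.15 without IgG2a replicate 3 and 0.014 without the 3 tumours.

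**Figure D3:**
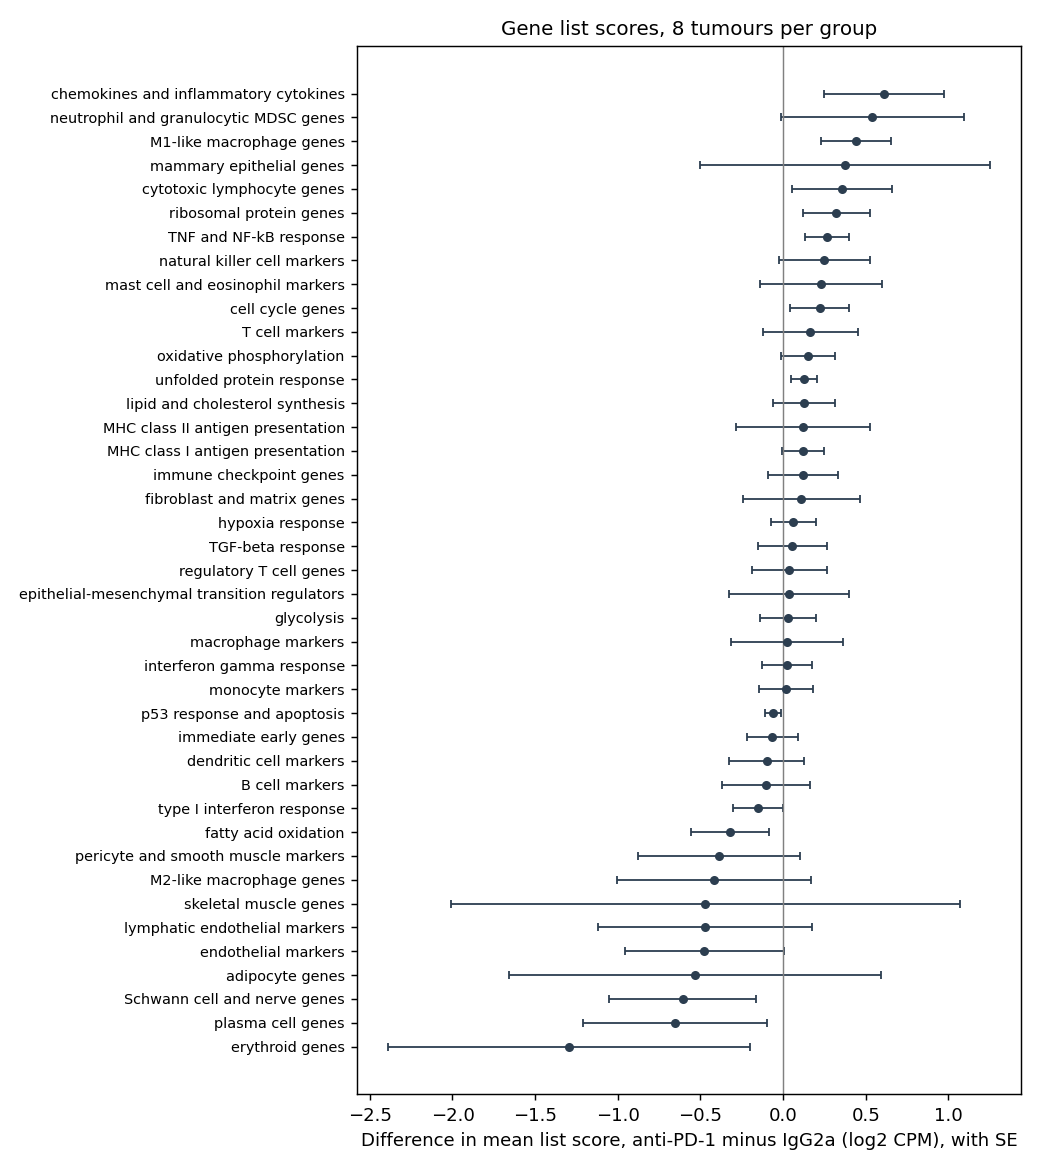
Differences in mean list score, anti-PD-1 minus IgG2a in log2 CPM, for the 41 scored lists, with points for the difference and bars for its SE over 8 tumours per group. The differences run from -1.30 for erythroid genes to 0.61 for chemokines and inflammatory cytokines, and none passed the exact permutation test after adjustment.

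Of the 41 lists, 26 had a positive and 15 a negative score difference. The exact permutation test called 0 after adjustment and 0 at an unadjusted p under 0.05. In the check with added shifts this test recovered 6 of 41 lists at 0.5 log2 units and 19 at 1, so differences of such sizes can be missed. Camera with a preset correlation of 0.01 called 14 lists, upward for ribosomal protein, chemokine, M1-like, cell cycle, neutrophil, TNF and NF-kB, oxidative phosphorylation, cytotoxic and unfolded protein response genes and downward for fatty acid oxidation, endothelial, adipocyte, erythroid and type I interferon genes. With an estimated correlation camera called 0 (smallest adjusted p = 0.905 with an estimated correlation), and fry called 0. The estimated correlations of the 14 lists ran from 0.17 for the unfolded protein response to 0.95 for erythroid genes, against the preset 0.01. Where members move together this far, p-values at the preset are too small. On log2(TPM + 1) scores 12 lists changed sign, among them the unfolded protein response at -0.032, immune checkpoint genes at -0.016, macrophage markers at -0.073 and the interferon gamma response at -0.12, and none passed. On the first principal component, with 45.3% of the variance, the group means differed by -14.5 (exact permutation p = 0.635). On the second, with 14.4% of the variance, they differed by -27.3 (exact permutation p = 0.0395, adjusted p = 0.0789 over 2 components). Anti-PD-1 replicate 6 lay at -90.7 on the second component and the next lowest tumour, IgG2a replicate 3, at -24.4. With these scores kept and tumours left out of the means, chosen after the values were seen, the difference was -16.2 without anti-PD-1 replicate 6 (exact permutation p = 0.0785, adjusted p = 0.157). Leaving out IgG2a replicate 3 gave -32.7 (exact permutation p = 0.0056, adjusted p = 0.0112) and leaving out anti-PD-1 replicate 2 gave -31.4 (exact permutation p = 0.0197, adjusted p = 0.0395). It was -18.5 without the 3 tumours (exact permutation p = 0.0152, adjusted p = 0.0303). The length correlation of the tumours ran much the same way as this component. Anti-PD-1 replicate 6 and IgG2a replicate 3 had -0.467 and -0.245. IgG2a replicates 8 and 4, at 24.9 and 21.4 on the component, had 0.404 and 0.341. Out of this order were IgG2a replicate 7, at 38.2 with 0.144, and IgG2a replicate 1, at 0.82 with -0.269. How far the component follows transcript length was not tested, so a group difference on it cannot be credited to treatment.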

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

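The tests of fat, muscle and read totals in single tumours were chosen only after the results were seen, as was that of the shortest transcripts, as was that of the splits for a count of 0 genes, while the tests of genes at 0 reads, of the length ratio and of the splits for the unadjusted count were written before. In each group of 8 the gap between the most extreme tumour and its neighbour, divided by the range, was compared with Dixon's 95% critical value for 8 values. Chance alone exceeds this in about 1 in 20 groups, and 35 of 216 did. Of these 18 were by IgG2a replicate 7, 10 by anti-PD-1 replicate 6, 4 by IgG2a replicate 3 and 3 by other tumours. Lists share members with each other and with the named genes, and many genes were named for a small p in these data. The rate of 1 in 20 is therefore only a rough guide to the 35.

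IgG2a replicate 7 was the tumour farthest from its group for endothelial markers at 0.781, erythroid genes at 0.561, macrophage markers at 0.578, regulators of epithelial-mesenchymal transition at 0.715, TGF-beta response at 0.568, immediate early genes at 0.729 and mammary epithelial genes at 0.528, as the highest, and for cell cycle genes at 0.855, glycolysis at 0.64 and ribosomal protein genes at 0.64, as the lowest. The same tumour was highest for Tnxb at 0.576, Alas2 at 0.551, Mrc1 at 0.558, Adgre1 at 0.582, Lep at 0.575 and Lrrc32 at 0.724, and lowest for Thoc1 at 0.608 and Cxcl10 at 0.685. It held 712 CPM of Adipoq and 609 CPM of Plin1, against medians of 1.86 and 1.30 CPM in the 13 tumours that did not stand apart, with 8494 CPM of the globin gene Hbb-bs. Of 18 tested adipocyte genes 100% lay 3 or more log2 units above the median of the other 7 IgG2a tumours, but the list was already known to be high, so this share restates the score and leaves a piece of fat pad in the sample open, as a hypothesis. Fewer tumour cells alone would raise every other cell type alike, which the data argue against. The adipocyte score minus the T cell score lay 8.40 log2 units above the median of this difference in the other 7 IgG2a tumours. In the other 15 tumours 2 SD of this difference is 2.09. The adipocyte score was already known to be high when this test was chosen, so a large value was foreseeable. The argument therefore rests on the T cell and cytotoxic lymphocyte scores. No biological explanation was tested, as the design gives the other 7 tumours of the group the same treatment.

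IgG2a replicate 3 was farthest from its group for skeletal muscle genes at 0.806, Camk2b at 0.549, Rasd2 at 0.612 and p53 response and apoptosis at 0.57, in each as the highest. Its Acta1, Ckm and Myh4 stood at 11777, 4440 and 6844 CPM, where the highest of the 13 tumours that did not stand apart held 39.2, 25.5 and 40.2 CPM. Of 17 tested muscle genes 100% lay 3 or more log2 units above the median of the other IgG2a tumours, but here too the list was already known to be high, so this share restates the score and leaves a piece of skeletal muscle in the sample open, as a hypothesis. RNA carried over from another of the 16 libraries is argued against, because the muscle score exceeded the highest of the others by 7.21 log2 units. The score was already known to be high when this test was chosen, so a large gap was foreseeable. A source among these libraries would still need a muscle score at least as high. No biological explanation was tested.

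Anti-PD-1 replicate 6 was lowest of its group for genes detected at 0.613, transcripts detected at 0.627, Adcy9 at 0.55, Abca8a at 0.549, Prf1 at 0.562 and Uqcrc2 at 0.769, and highest for oxidative phosphorylation at 0.724, ribosomal protein genes at 0.645, Psme1 at 0.568 and Cox4i1 at 0.688. Fewer reads are argued against, since its genes held 74361796 reads and the median of the other tumours was 68099721. Of genes expected at 10 to 50 reads 31.4% had 0 reads, against 6.92 to 15.6% elsewhere, just past the bound of 2 times the highest other. Few transcripts detected make a high share at 0 reads likely, so this share largely restates the pattern. It leaves fewer distinct molecules in the library open, as a hypothesis. Loss of long transcripts as the whole cause is argued against, since 26.6% of the shortest 25% of these genes also had 0 reads, against at most 13.6% elsewhere. Whether long transcripts were lost in part was left open by the share at 0 reads in the longest 25% divided by that in the shortest 25%. This ratio was 1.42, inside the range of 0.354 to 1.57 of the other tumours and short of the bound of 1.5. The length correlation of anti-PD-1 replicate 6 was -0.467, the lowest of the 16 tumours, with IgG2a replicate 1 next at -0.269. That is the direction a loss of long transcripts would give. A response of this animal to the antibody was not tested.

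Anti-PD-1 replicate 5 was the highest of its group for adipocyte genes at 0.676 and for fibroblast and matrix genes at 0.536, and anti-PD-1 replicate 8 the lowest for Pdk4 at 0.5263. For the count of genes called by edgeR, the real grouping gave 0 genes and the highest of the other splits 0, and since every split reaches a count of 0, all 100 drawn did so and the comparison decides nothing. For genes at an unadjusted p under 0.05 chance cannot be excluded, since the real grouping gave 1836, the highest of the other splits 4136, and 19 of 100 splits gave as many. Splits that kept IgG2a replicates 3 and 7 on one side had a median of 1528 such genes, and those that parted them 673.5. Their placing alone does not set the count, since a split that parted them gave 3029. For the real grouping edgeR gave 2580 such genes without the 3 tumours that stood apart and 2607 without IgG2a replicate 3.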

How the results depend on the processing

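No gene passed the adjusted threshold under edgeR with any scaling, filter, length offset, covariate or left-out tumour, nor with limma-voom. DESeq2 called 4 genes, and Cxcl5 passed there alone, while its log2 fold change stayed between 2.39 and 3.86 over 27 settings with adjusted p from 3.5e-04 to 0.669. The count at an unadjusted p under 0.05 was 1836 and became 1011 with limma-voom, 3421 with quality weights, 4293 with no filter, where more genes were tested, and 3442 with quality weights without the 3 tumours that stood apart. It was 1209 without anti-PD-1 replicate 6 and ran from 1162 (without IgG2a replicate 7) to 2607 (without IgG2a replicate 3). Without the 3 tumours edgeR gave 2580 (1128 higher, 1452 lower). Lower estimates outnumbered higher ones by 1276 to 560 with all tumours, by 507 to 504 with limma-voom and by 994 to 765 with DESeq2, while without IgG2a replicate 7 higher ones outnumbered lower ones by 607 to 555. The cause was not tested. At an adjusted p of 0.1 edgeR called 0 genes, against 537 with quality weights without the 3 tumours. No list passed the permutation test under any score or left-out tumour, while camera with the preset correlation called 14 lists, 9 upward and 5 downward, and 12 without the 3 tumours, 12 upward and 0 downward. With an estimated correlation, run on all tumours only, camera called 0 (smallest adjusted p = 0.905). The estimated correlations of the 14 lists ran from 0.17 to 0.95, so p-values at the preset of 0.01 are too small. None was estimated without the 3 tumours, so the 12 calls there rest on the preset alone. The difference on the first component was -14.5. With components taken anew from the tumours kept, it was 32.7 without the 3 tumours (exact permutation p = 0.0682). With each tumour left out in the same way it ran from -25.7 to 12.9. These axes are not that of all 16 tumours, so a change of sign there is not a reversal along the same axis. On the second component, with the components of all 16 tumours kept and single tumours left out of the means, chosen after the values were seen, the difference of -27.3 (adjusted p = 0.0789) stayed negative. It ran from -32.7 without IgG2a replicate 3 (exact permutation p adjusted to 0.0112) to -16.2 without anti-PD-1 replicate 6 (adjusted to 0.157), and passed also at -31.4 without anti-PD-1 replicate 2 (adjusted to 0.0395) and at -18.5 without the 3 tumours (adjusted to 0.0303). The length correlation of the tumours ran much the same way as this component. How far the component follows it was not tested. No paired analysis was possible because the labels give animal numbers and pair no tumours. For named genes 35 of 1637 values changed sign, in 15 of 61 genes, and 12 of these, in 6 genes, had an unadjusted p under 0.05 in either fit. For lists 90 of 943 did, in 28 of 41 lists, and 0 of these had. In the values that follow a sign changed, and the cause was not tested. With DESeq2 it was Slc2a4 0.29. With quality weights these were Pdk4 0.61, Pdcd1 -0.28, Cd274 -0.18, Cd8a -0.067, Cd4 0.17, Gzmb -0.028, Nos2 -0.33, Mrc1 0.078, Lep 0.67, Adipoq 1.11, Plin4 1.01. Without the 3 tumours these were Pdk4 0.17, Tpbgl 0.039, Pdcd1 -0.20, Cd4 0.097, Gzmb -0.084, Mrc1 0.23, Lep 1.09, Adipoq 0.63, Uqcrc2 0.014, Slc2a4 0.46, Plin4 0.73, and for lists B cell markers 0.13, plasma cell genes 0.041, M2-like macrophage genes 0.40, dendritic cell markers 0.017, immediate early genes 0.077, glycolysis -0.11, lipid and cholesterol synthesis -0.083, adipocyte genes 0.91, endothelial markers 0.13, pericyte and smooth muscle markers 0.26, lymphatic endothelial markers 0.30, skeletal muscle genes 1.06, Schwann cell and nerve genes 0.074, erythroid genes 0.056. With log2(TPM + 1) scores these were immune checkpoint genes -0.016, regulatory T cell genes -0.083, macrophage markers -0.073, monocyte markers -0.11, interferon gamma response -0.12, hypoxia response -0.074, glycolysis -0.069, lipid and cholesterol synthesis -0.018, epithelial-mesenchymal transition regulators -0.10, TGF-beta response -0.11, mammary epithelial genes -0.012, unfolded protein response -0.032. With log2(TPM + 0.1) these were immune checkpoint genes -0.028, regulatory T cell genes -0.11, macrophage markers -0.081, monocyte markers -0.12, interferon gamma response -0.13, hypoxia response -0.065, glycolysis -0.077, lipid and cholesterol synthesis -0.016, epithelial-mesenchymal transition regulators -0.052, TGF-beta response -0.097, unfolded protein response -0.035. With medians over members these were macrophage markers -0.20, dendritic cell markers 0.0041, interferon gamma response -0.019, epithelial-mesenchymal transition regulators -0.040, TGF-beta response -0.15, p53 response and apoptosis 0.067. With members scaled to an SD of 1 these were immediate early genes 0.0047, epithelial-mesenchymal transition regulators -0.081, p53 response and apoptosis 0.0078. With each tumour left out in turn the ranges were Pdcd1 -0.20 to 0.27, Cd274 -0.024 to 0.44, Cd4 -0.58 to 0.036, Foxp3 -0.31 to 0.0062, Gzmb -0.042 to 0.38, Lep -5.22 to 0.75, T cell markers -0.0015 to 0.26, regulatory T cell genes -0.084 to 0.12, B cell markers -0.22 to 0.049, macrophage markers -0.10 to 0.26, M2-like macrophage genes -0.55 to 0.036, monocyte markers -0.055 to 0.11, interferon gamma response -0.074 to 0.076, MHC class II antigen presentation -0.083 to 0.28, immediate early genes -0.13 to 0.049, glycolysis -0.11 to 0.086, adipocyte genes -1.01 to 0.39, fibroblast and matrix genes -0.030 to 0.39, epithelial-mesenchymal transition regulators -0.11 to 0.33, TGF-beta response -0.017 to 0.19, pericyte and smooth muscle markers -0.51 to 0.014, skeletal muscle genes -0.88 to 0.90. Depth was 59036535 reads or more per tumour, which left 16154 of 47311 genes with enough reads to test, and nothing is said here of the others.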

Other observations

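The tests of the hypotheses below were chosen only after the levels of these genes and lists were seen. Genes of the CXC chemokine cluster on chromosome 5 were looked at together after the value of Cxcl5 was seen. Beside Cxcl5 at 90759360, Cxcl3 at 90786103 had 38.9 ± 57.0 CPM under anti-PD-1 and 9.53 ± 7.06 CPM under IgG2a (SD, n = 8 each), a log2 fold change of 2.03 ± 0.86 (SE). Cxcl2 at 90903871 had a log2 fold change of 1.65 ± 0.80 and Cxcl1 at 90891241 one of 0.97 ± 0.47 (SE). The monocyte chemokine genes Ccl2 and Ccl7 had 0.54 ± 0.21 and 0.58 ± 0.19 (log2 fold change and SE), with 8 of 8 treated tumours above the IgG2a median for each. None passed edgeR's quasi-likelihood test, with adjusted p = 0.434 for each. These genes were picked from the 26 chemokine and inflammatory cytokine genes, of which 18 had higher and 8 lower estimates. At an unadjusted edgeR p under 0.05 these counts were 10 and 2. The score difference of that list was 0.44 without anti-PD-1 replicate 1. Of the genes named here only Cxcl5 was also estimated with tumours left out.

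One hypothesis was that Cxcl5 rises and falls with neutrophil marker levels. Across the 16 tumours the neutrophil list and Cxcl5 had a Pearson r of 0.53 (permutation p = 0.0357, adjusted p = 0.0624 over 7 relations) and a Spearman rho of 0.465 (permutation p = 0.0708, adjusted p = 0.124). Without the 2 tumours farthest from the median r was 0.50, and within groups it was 0.63 under anti-PD-1 and 0.30 under IgG2a. The relation may exist, but it missed the threshold after adjustment, so the test left it open.

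A second hypothesis was that the interferon gamma response follows T cell content. The T cell score and the interferon gamma response score, which share no member, had a Pearson r of 0.66 (permutation p = 0.0048, adjusted p = 0.0112) and a Spearman rho of 0.621 (permutation p = 0.0117, adjusted p = 0.0406) across the 16 tumours. Without the 2 tumours farthest from the median r was 0.50, within groups it was 0.64 under anti-PD-1 and 0.71 under IgG2a, and without the 3 tumours that stood apart it was 0.72. The values are consistent with the hypothesis, and a shared share of immune cells in the piece of tumour could give the same relation.

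In the same family of 7 relations the T cell score went with MHC class II presentation, at a Pearson r of 0.73 (permutation p = 0.0012, adjusted p = 0.0042) and a Spearman rho of 0.591 (permutation p = 0.0174, adjusted p = 0.0406), with r = 0.61 without the 2 farthest tumours. Pdcd1 went with the cytotoxic lymphocyte score, at a Pearson r of 0.87 (permutation p = 3.0e-05, adjusted p = 2.1e-04) and a Spearman rho of 0.832 (permutation p = 8.0e-05, adjusted p = 5.6e-04), with r = 0.80 without the 2 farthest tumours, 0.93 within anti-PD-1 and 0.88 within IgG2a. The T cell score did not go detectably with the cell cycle score (Pearson r = 0.23, permutation p = 0.361, and Spearman rho = 0.147, permutation p = 0.587) or the fibroblast score (Pearson r = 0.23, permutation p = 0.378, and Spearman rho = 0.174, permutation p = 0.518), nor the neutrophil score with the T cell score (Pearson r = -0.09, permutation p = 0.738, and Spearman rho = -0.203, permutation p = 0.450). Without their 2 farthest tumours these r were 0.35, -0.25 and -0.04, and without the 3 tumours that stood apart -0.03, 0.65 and -0.04. Within groups the r with the fibroblast score was 0.75 under anti-PD-1 and -0.07 under IgG2a, that with the cell cycle score -0.56 and 0.41, and that of neutrophil and T cell scores 0.35 and -0.67. For all 3 the adjusted p was 0.440 or more.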
